A study of Mus musculus with 2 samples.

How the data were processed

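ERα ChIP-seq was performed on mammary gland pads of mice aged 5 to 6 weeks. Per the labels' protocols, the tissue was fixed, the sonicated chromatin was immunoprecipitated with an ERα antibody, and sequencing libraries were amplified by 15 cycles of PCR, with fragments of about 250 bp cut from a gel. The ChIP library pools 6 mice. The control is a library of whole cell extract. Each group has 1 library, so no test between conditions and no replicate error can be given.

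Per the submitters' processing notes, BWA was used, with the mouse assembly mm9, and MACS 1.4.1. The settings of these tools, and the version and settings of CCAT, are not given in the sources used here. The authors deposited 2 region lists of the ChIP library, one from MACS and one from CCAT, whose name the file carries. The deposited MACS list holds a score per peak, which in the format of this caller is 10 times the negative log10 of the peak's p-value. Its lowest value is 70.03 and its highest 3100. The deposited CCAT list holds 1 value per region between 0.005 and 1, in 14 levels, which was read from its range and order as a false discovery rate (FDR). Neither file has a header. The starts and ends of the CCAT regions all fall on a 50 bp grid. Neither list gives read counts, a fold enrichment or a peak summit, so the depth is unknown and an interval or detection limit based on reads cannot be given. Such lists depend on the caller's threshold, on how reads that match several places were treated, and on the chromosome lengths supplied. None of these choices is recorded in the lists.

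The lists were read as BED files and starts were moved to count from base 1. CCAT positions listed more than once (275 positions, 46 of them with more than 1 FDR) were used once, at the FDR of the first line that listed them. Overlap meant at least 1 bp. Expected overlaps came from 1000 random placements of the MACS peaks, each on its own chromosome with its width kept, between the first called position and the mm9 chromosome length. Chromosome lengths came from the tables in GenomeInfoDb 1.38.1. The p-value of a placement test is one-sided. Differences of medians within a list were tested by permuting regions 100000 times, two-sided. Regions within a library are not replicates, so these tests describe the lists and not variation between animals. Shares have 95% Wilson intervals, which cover counting error alone. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap code was tested on simulated data for the comparison of the callers. With 59.9% of 881 simulated peaks placed on CCAT regions it found 60.8% overlapping, against 60.9% expected, and it differed from a direct search in 0 of 200 intervals.

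The design, the alternatives and the rule for naming regions were fixed before the data were examined, except those described as chosen after. The width of MACS peaks by score and the classes of CCAT FDR were not in that design. Neither were the score tests of MACS peaks without a CCAT region. The rule named the 10 MACS peaks with the smallest p-value, with ties ordered by position, and the 10 with the highest fold, which the list does not give. Other regions are named because a count singled them out after their values were seen. The planned CCAT score and fold were not in the list, and the FDR was used in their place. A planned search for 22 motifs, the position of regions relative to genes, and 14 gene lists, among them 28 known ERα target genes, needs an mm9 sequence or annotation. None was used here, and these analyses were not run. A gene table on another assembly was not used, because coordinates of different assemblies cannot be mixed. Alternatives tried were stricter thresholds for each caller, merging of regions within 500 bp, a cover of at least 50% of the MACS peak, a distance of 1 kb, and the removal of repeated positions, clusters or chromosome ends.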

Results

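Estrogen receptor alpha (ERα) is the nuclear receptor through which estrogens act on the mammary epithelium during puberty. Its binding to chromatin was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mammary gland pads of mice on the C57BL/6J background, taken at 5 to 6 weeks of age. The series held 1 ERα ChIP library, made from tissue pooled from 6 mice, and 1 whole cell extract library that served as the control. The comparison implied by the design is therefore the ChIP against the whole cell extract, which would give the positions that the antibody enriched. The authors deposited 2 lists of regions for the same ChIP library, from the peak callers MACS and CCAT. The settings of the callers are not given in the sources used here. Because each group had 1 library, no region has a replicate error, and scores and false discovery rates are those given by the callers. The lists give no read counts, so the sequencing depth behind each region is unknown. Positions refer to the mouse assembly mm9 and are given from base 1. An mm9 sequence or gene annotation was not used here, so regions are named by position and not by gene.

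MACS called 881 peaks from the ERα ChIP on chromosomes 1 to 19, X and Y, which covered 0.357 Mb of the genome. The peaks were narrow, with a median width of 315 bp and an interquartile range of 213 to 465 bp. Their scores, which are 10 times the negative log10 of the p-value, ran from 70.03 to 3100 with a median of 175, and 8 peaks shared the highest score. Strong peaks were wider than weak ones: with the peaks split by score into 4 parts of similar size, the median width was 219 bp in the weakest part, then 293 and 377 bp, and 515 bp in the strongest. Peaks within 5 kb of each other formed 809 separate loci, of which 780 held a single peak.

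The 10 MACS peaks with the smallest p-values lay on 8 different chromosomes. How reads that match several places were treated is not recorded, and no motif was searched for. These peaks are therefore ranked by score and not shown to be ERα sites. Of the 8 peaks at the highest score, 1 was on chromosome 2 (158348656 to 158349330), 1 on chromosome 7 (74606847 to 74607531) and 1 on chromosome 8 (81638274 to 81639055). A further 3 were on chromosome 10 (69622190 to 69622954), chromosome 11 (87968886 to 87969599) and chromosome 16 (25220473 to 25221203). These 6 peaks were between 675 and 782 bp wide. The remaining 2 were on chromosome 17. The first of these (13744631 to 13746053) was 1423 bp wide and shared its locus with a second peak. The other (39979929 to 39985784) spanned 5856 bp, against a median width of 748 bp for the 8 peaks. The next peaks by score were on chromosome 11 (70096941 to 70097706, score 3024.21) and chromosome 6 (100009708 to 100010394, score 3013.29). Each of these 10 peaks overlapped a CCAT region with a false discovery rate of 0.005, the lowest value in that list.

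A small number of loci held groups of adjoining peaks. In 10 clusters of at least 3 peaks, spaced by no more than 5 kb, lay 63 peaks, or 7.15% of the list, whereas 1000 random placements of the peaks on their own chromosomes put at most 3 peaks in such clusters (permutation p = 0.000999, one-sided, the smallest that 1000 placements can give). The placements moved each peak separately, although adjoining peaks of a cluster are not independent, so this p-value is too small. The largest held 20 peaks on chromosome 11 between 3025592 and 3069294, and 85% of that span was covered by peaks. Clusters of 5 and 3 peaks followed on the same chromosome, up to 3100094. Near the end of chromosome X, 12 peaks lay between 166423747 and 166447010, with a highest score of 1115.09. Clustered peaks had a median width of 968 bp, against 298 bp for the 780 single peaks. At equal score they were 2.83 times as wide (permutation p = 1e-04, two-sided, 10000 resamples within 10 score classes, the smallest these can give). This test counts peaks of a cluster as independent. The 63 peaks came from 10 clusters, with 20 in the largest, so its p-value is too small. Overlap with CCAT regions of a false discovery rate of at most 5% was compared up to the last CCAT region of each chromosome. Such a region was overlapped by 10 of 51 clustered peaks (19.6%, 95% Wilson interval 11.0 to 32.5%). Of the single peaks, 224 of 754 did so (29.7%, 26.6 to 33.1%, Fisher's exact test over peaks, two-sided p = 0.151). All 10 clustered peaks lay in the cluster of 6 peaks on chromosome 13 and that of 4 on chromosome 17. The interval and Fisher's test also count peaks of a cluster as independent, so they cannot decide whether clusters differ from single peaks. Of the 63 clustered peaks, 35 lay within 200 kb of the first called position of their chromosome, as did 4 of the single peaks. The cluster definition was chosen after the data were seen.

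**Figure D1:**
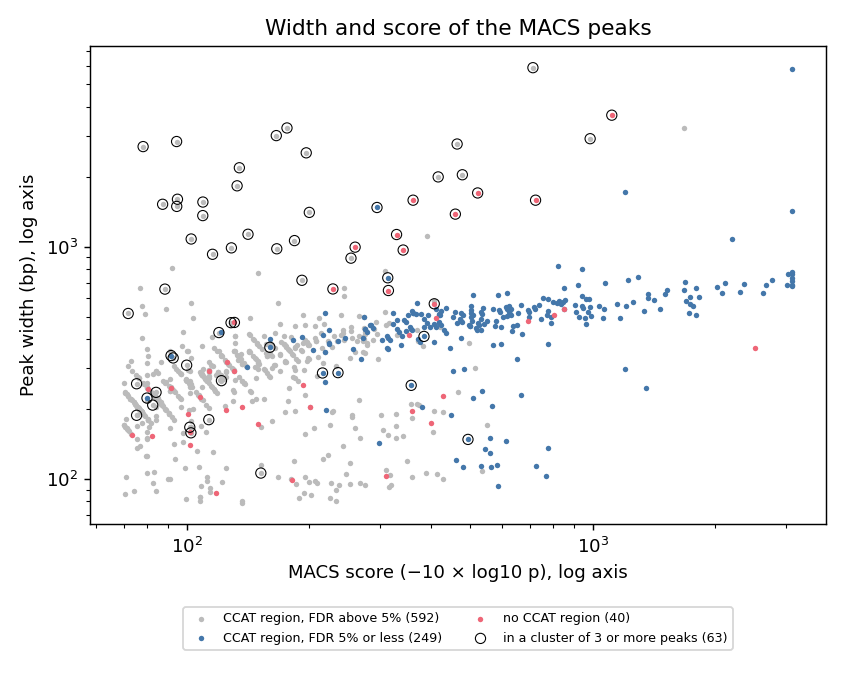
Width (bp, log axis) against MACS score (log axis) for each of the 881 MACS peaks, one point per peak, coloured by the CCAT region that it overlaps, with circles around the 63 peaks in clusters of 3 or more. Most peaks follow a band in which width rises with score, most clustered peaks lie above it, and a second group of narrow peaks lies below it.

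CCAT listed 55098 regions, far more than MACS, but few of them had a low false discovery rate. In all, 54223 regions, or 98.4%, carried a false discovery rate of 1, and 875 a lower one. A rate of at most 5% was reached by 244 regions and a rate of at most 1% by 179. The regions were wider than MACS peaks, with a median of 700 bp and an interquartile range of 600 to 850 bp, and covered 41.9 Mb, or 1.58% of chromosomes 1 to 19, X and Y. Of the deposited lines, 428 repeated the position of an earlier line, which left 54670 distinct regions. The comparisons that follow use each position once, with the rate on the first line that listed it.

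To ask how far the lists name the same sites, the peaks of MACS were set against the regions of CCAT. Of the 881 MACS peaks, 841 overlapped a CCAT region by at least 1 bp, which is 95.5% (95% Wilson interval 93.9 to 96.6%). Random placement of the peaks gave a median of 2.61% and a highest value of 4.09% (permutation by 1000 placements, one-sided p = 0.000999, the smallest they can give). In the other direction, 792 of the 54670 CCAT regions, or 1.45% (1.35 to 1.55%), overlapped a MACS peak. Both lists come from the same reads, so this overlap measures how far the callers' lists coincide and is not a replication. The intervals cover counting error alone, and neighbouring regions are not independent.

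The share of CCAT regions with a MACS peak fell as the false discovery rate rose, from nearly all regions at a low rate to few at a rate of 1. A MACS peak lay in 236 of 239 regions with a rate of at most 5% (98.7%, 95% Wilson interval 96.4 to 99.6%), in 265 of 292 with a rate from 0.106 to 0.298 (90.8%, 86.9 to 93.6%) and in 162 of 320 with a rate from 0.531 to 0.791 (50.6%, 45.2 to 56.1%). Among the 53819 regions with a rate of 1, a peak lay in 129 (0.240%, 0.202 to 0.285%). The 3 regions with a rate of at most 5% and no peak were the last regions of chromosomes 2, 5 and 11, and each ran past the end of its mm9 chromosome, by 413, 591 and 594 bp. CCAT regions with a MACS peak had a median false discovery rate of 0.210, against 1 for those without (permutation test over regions, 100000 resamples, two-sided p = 1e-05, the smallest these can give). They were also wider, with a median of 1200 bp against 700 bp (same permutation test, p = 1e-05).

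**Figure D2:**
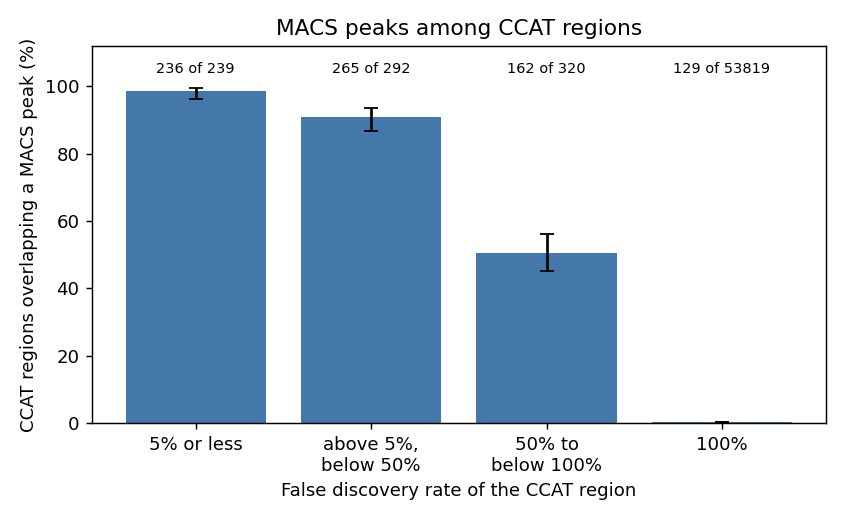
Percentage of distinct CCAT regions that overlap a MACS peak, by the false discovery rate of the region. Bars are percentages, error bars are 95% Wilson intervals, and the numbers above give regions with a peak of all regions in the class, from 236 of 239 down to 129 of 53819.

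The support that CCAT gave to the MACS peaks was uneven. Of the 881 MACS peaks, 249 (28.3%) overlapped a region with a rate of at most 5%, and their median MACS score was 549. A further 287 overlapped, at best, a region with a rate from 0.106 to 0.298, with a median score of 165. Another 170 reached a rate from 0.531 to 0.791, with a median score of 103. For 135 peaks (15.3%) the best overlapping region had a rate of 1, and their median score was 88.8.

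The 40 MACS peaks without a CCAT region spanned weak and strong scores. Their median score was 245, against 174 for the 841 that overlapped (permutation test, 100000 resamples, two-sided p = 0.0504). This order rested on the 12 clustered peaks near the end of chromosome X. With clusters left out, the 28 remaining peaks had a median score of 143, against 176 for 790 that overlapped (same permutation test, p = 0.427). They included a peak on chromosome X (166527151 to 166527517) with a score of 2512.79, 1 on chromosome 16 (96032600 to 96033140) with a score of 849.7, and 1 on chromosome 17 (84313304 to 84313811) with a score of 802.91. All 40 lay past the last CCAT region of their chromosome, on chromosomes 13 to 19 and X. On these 8 chromosomes the CCAT list stopped between 0.984 and 17.9 Mb before the end of the mm9 sequence, 72.7 Mb in total, and 14 of the 40 peaks were on X. Up to the last CCAT region of each chromosome, all 841 MACS peaks overlapped a CCAT region. The score tests of the peaks without a CCAT region were chosen after the data were seen.

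**Figure D3:**
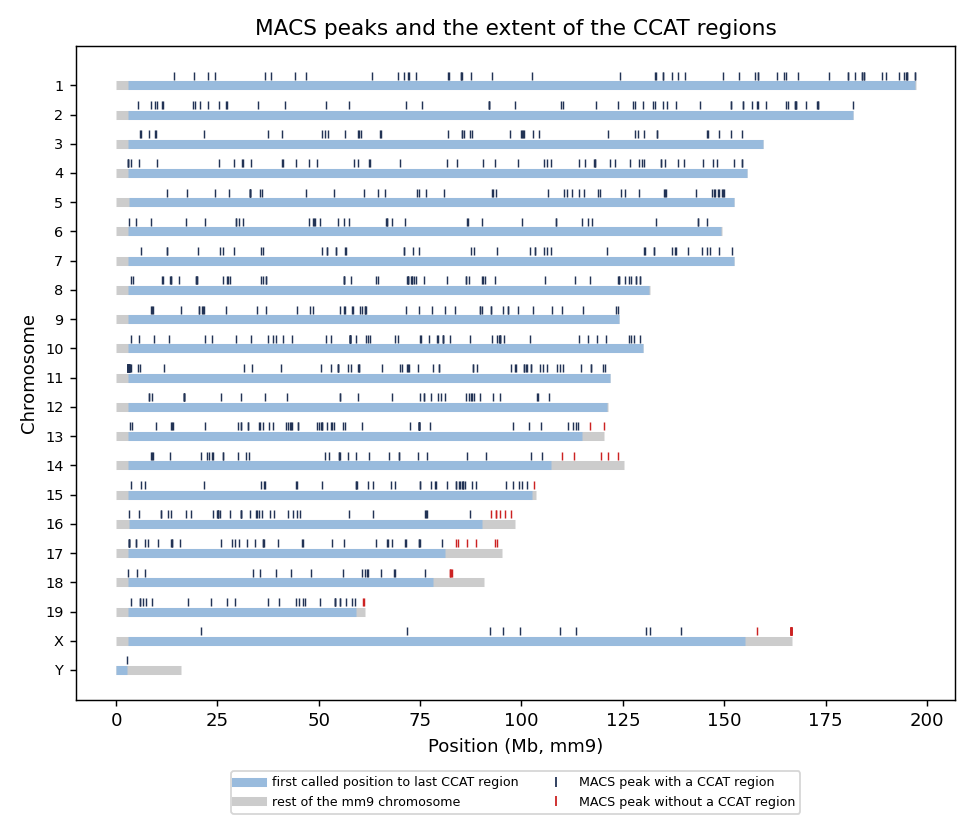
Positions of the MACS peaks (ticks) along the mm9 chromosomes (Mb), with the stretch from the first called position to the last CCAT region in blue and the rest of each chromosome in grey. The 40 peaks without a CCAT region, in red, lie in the grey ends of chromosomes 13 to 19 and X.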

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

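The overlap of MACS peaks with CCAT regions stayed above random placement under every alternative run, at 81.0% with only the top CCAT regions, as many as there are MACS peaks (ties in FDR taken in file order), and at 94.5% for the stronger MACS peaks. It was 95.5% with at least 50% of the peak covered and with a distance of 1 kb. Among alternatives chosen after the data were seen, it was 28.3% with CCAT regions of an FDR of at most 5%, 96.6% without clusters, and 100% up to the last CCAT region of each chromosome. The MACS list gives no FDR, so the stricter MACS list was its stronger part by p, which by construction holds 440 of 881 peaks. An FDR of at most 1% left 179 of the 55098 CCAT regions. Merging within 500 bp left 833 MACS and 53623 CCAT regions. The lower FDR of CCAT regions with a MACS peak kept its direction with repeated lines (difference in medians -0.718 against -0.791). Motifs, gene positions and gene lists, with their other settings, were not run, for want of an mm9 sequence or annotation. No library could be left out, and no paired analysis was possible because each group has 1 library. The depth of the libraries is unknown, so it was not tested which of the weaker peaks it limits.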

Other observations

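All tests in this part were chosen after the data were seen, except that of CCAT regions around narrow peaks, whose outcome was predicted before it was computed. MACS loci, which are MACS peaks merged within 5 kb and are not shown to be ERα sites, were spread unevenly over the genome. Of 809 loci, 93 (11.5%, 95% Wilson interval 9.48 to 13.9%) had another locus within 50 kb, against a median of 3.21% in 1000 random placements (permutation by placement, one-sided p = 0.000999, the smallest they can give). Within 100 kb the share was 16.3% against 6.43% (permutation p = 0.000999). The clusters of 20, 5 and 3 peaks on chromosome 11 lie within 50 kb of one another and add to these counts. The neighbour counts were not repeated without clusters. CCAT regions with an FDR of 1 also lay near MACS loci more often than near random positions. Such a region was found at 1 to 10 kb from 394 of the 780 loci, with 1 or more peaks, that end at least 10 kb before the last CCAT region of their chromosome (50.5%, 47.0 to 54.0%), against a median of 32.9% and a highest value of 38.5% in 1000 placements (permutation p = 0.000999). The random placements in these tests did not leave out assembly gaps or sequence to which reads cannot be assigned. The differences may therefore partly reflect where regions of any kind can be called.

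By chromosome, relative to length, chromosome 11 held 55 loci where 37.1 were expected (1.48 times, exact binomial test, p = 0.0432 after Benjamini-Hochberg adjustment over 21 chromosomes). These loci include the clusters of 20, 5 and 3 peaks between 3025592 and 3100094, and the excess was not tested without them. Chromosome X held 13 where 51.0 were expected (0.255 times, exact binomial test, adjusted p = 3.66e-09). The other chromosomes had an adjusted p above 0.05. The test treats loci as independent, and loci lie closer together than random placement gives, so its p-values are too small. The single peak on chromosome Y (2652197 to 2652331) had a score of 544.43 and a width of 135 bp, where 68 other single peaks with a score within 1.2-fold had a median width of 468 bp and 7 of them were narrower.

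All 40 MACS peaks without a CCAT region lie on chromosomes 13 to 19 and X, past the point where the CCAT list ends. Weak peaks missed by CCAT are argued against as an explanation, because 0 of 596 peaks on chromosomes 1 to 12, where the list reaches the mm9 end, lacked a CCAT region, among them 0 of 144 peaks with a score of at most 102. A candidate explanation is CCAT run with the chromosome lengths of the human hg19 assembly. All 40 peaks start past the hg19 length of the chromosome with the same name, and these 8 are the chromosomes among 1 to 19 and X that are shorter in hg19 than in mm9. On them the last CCAT region ended 3.90 to 136 kb before the hg19 length. With the limit of each of these 20 chromosomes set at the shorter of its mm9 length and its length in another assembly, hg19 came closest of 17 assemblies, with a summed distance from the last CCAT region to the limit of 1395 kb, against 8075 kb for hg38 and 73648 kb for mm9 alone. Y was left out of this comparison, because it is longer in hg19 than in mm9. There the last CCAT region ended at 2652900, 13.2 Mb before the mm9 length. The only MACS peak on Y ended at 2652331, so both lists stop near the same point. Assembly gaps were not examined, so Y counts neither for nor against the candidate explanation.

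Few MACS loci were found on chromosome X, and the shortfall held up to the last CCAT region (0.211 times the number expected from length), for loci that hold a peak with a score above the median (0.154) and without clusters (0.233). Counting every peak in place of loci gave 0.432 times, and every peak with a score above the median 0.504 times, since the cluster near the end of X holds 12 of its 24 peaks. A lower number of callable regions of any kind on X is argued against as the whole cause, because, up to the last CCAT region of each chromosome and among autosomes and X, X held 10 of 780 MACS loci (1.28%) but 4.48% of CCAT regions with an FDR of 1 (odds ratio 0.277, Fisher's exact test over regions, two-sided p = 1.06e-06). A lower read depth on X cannot be told apart from a real scarcity of sites. The median score of the 13 loci on X differed by -77.2 from that of the 795 autosomal loci (95% bootstrap interval -102 to 98.7), and 13 loci are too few to settle it. The sex of the mice is not in the labels used here, and a biological scarcity of ERα sites on X stays open and untested.

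Among 291 single MACS peaks with a score above 250, widths fell into separate groups. A width below 250 bp, the fragment size in the labels, was found for 58, while 9 were 250 to under 350 bp wide and 103 were 450 to under 550 bp wide. The strongest narrow peak was on chromosome 14 (86598714 to 86598960), with a score of 1350.27, and overlapped a CCAT region with an FDR of 0.005. The groups were compared in the 280 peaks that end at least 10 kb before the last CCAT region of their chromosome. A difference in score alone is argued against: a CCAT region with an FDR of at most 5% lay at 18 of 53 narrow (34.0%) and 193 of 227 wide peaks (85.0%). This was a difference of -44.4 percentage points within 10 score classes (permutation p = 1e-04, two-sided, the smallest 10000 resamples can give). Whether both groups mark the same kind of site stays open, since a CCAT region with an FDR of 1 at 1 to 10 kb was found for 39.6% of 53 narrow and 53.7% of 227 wide peaks (-11.5 percentage points within 10 score classes, permutation p = 0.153). Reads stacked on few positions, such as PCR duplicates, could give narrow peaks of this kind, which the lists hold no reads to test, and the design offers no biological explanation to set against it.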
